A study of Mus musculus with 4 samples.

How the data were processed

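RNA from 4 mouse tumours labelled MYC;PMEPA1 overexpression was extracted with Trizol, treated with DNase, selected for poly-A and made into libraries with the TruSeq RNA kit, per the labels' protocols. FastQC 0.11.8 and the genome build GRCm38 are named in the submitters' processing notes. The aligner and the counting program are not given in the sources used here, nor is whether counting used strand, so reads of overlapping antisense genes cannot be told apart.

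Each deposited table holds 33984 RefSeq transcript rows, the same in all 4 libraries, 29455 with protein-coding and 4529 with non-coding accessions, for 24063 gene symbols. The authors' deposited counts are whole numbers of reads per transcript row. The deposited FPKM column, so named per the file headers, was found to equal the counts divided by the file's own count total and by a transcript length, which came out whole within 0.01 bases for 100% of detected rows. The deposited TPM column, so named per the file headers, was found to sum to 1000000 in each library. FPKM and TPM were used only to check the unit and to recover the transcript lengths. The counts over all rows were 1.487, 1.484, 1.458 and 1.434 times the gene totals in tumours 1, 5, 9 and 10. Of 4686 detected genes with more than 1 detected row, 946 (20.2%) had rows with identical counts in all libraries. Reads were thus counted on more than 1 isoform of a gene. For this reason each gene was represented by its transcript row with the highest mean count, a choice made after the tables were seen, and the sum over rows was tried as an alternative. The FPKM and TPM denominators hold these repeated reads too. Mitochondrial genes and the T cell receptor and immunoglobulin constant genes of the lists have no row under their symbols and were not analysed here. Rows that share reads, such as Hba-a1 with Hba-a2, are uncertain, and removing symbols with counts equal to another symbol's was tried as an alternative.

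The count tests were run in R 4.3.3 with edgeR 4.0.16. Counts were scaled by TMM, with factors of 1.102, 1.031, 1.098 and 0.8017 for tumours 1, 5, 9 and 10. Scaling by total counts alone would move the median gene by 0.14, 0.04, 0.13 and -0.32 log2 units in these tumours, and all changes are given relative to TMM. DESeq2 size factors moved it by at most 0.01. CPM values use the TMM-scaled library sizes, and log2 CPM adds a prior count of 2. A gene with a mean of at least 1 CPM over the 4 tumours counted as expressed. A gene high in 1 tumour can pass this filter through that tumour alone, which favours high list scores there. Counting noise was tested with a Poisson heterogeneity chi-square test per gene, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each tumour was tested against the other 3 with edgeR's two-sided quasi-likelihood test (robust), adjusted by Benjamini-Hochberg over all genes and the 4 tumours together. No test between conditions exists with 1 group, and an exact sign-flip test over 4 tumours cannot give a two-sided p under 0.125.

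Before the data were examined, 34 gene lists with 488 entries were fixed. Of these entries, 468 have a row, 4 of them under an older symbol found through RefSeq synonyms, a search made after the lists had been scored once, and 20 have none. The 25 lists with at least 5 expressed members were scored in each tumour as the mean over members of log2 CPM minus the member's 4-tumour mean. The score's percentile was taken among 10000 random lists of the same size matched on mean expression in 20 bins, and scores among the lowest or the highest 0.5% were called apart. The other 9 lists (T cells, regulatory T cells, cytotoxic and NK cells, B and plasma cells, dendritic cells, mitochondrial genome, pancreatic acinar, mesothelial and sex-linked genes) were described by their levels. The genes named were fixed by rule: Myc and Pmepa1, the 10 genes with the highest mean CPM, and of each list the 3 expressed members with the highest mean CPM and the 1 with the largest SD. The rule also took members of the TGF-beta and exhaustion lists where the text gives counts over them, and called genes of the 1 against 3 tests, of which there were none. Gpc3, Dlk1, Peg3, Igf2bp1, Cd274, Mug1, Cyp2c29, Marco, Timd4, Clec4g, Oit3, Lrat, the adult hepatocyte list and the genes added in the closing section were chosen after their values were seen. Some genes that the rule takes are not reported here. Coordinates are those of GENCODE M21 on GRCm38.

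The count tests were run on simulated counts with the real means and library sizes. With counting noise alone, 0% of 13129 genes were called beyond it. With 200 genes changed in tumour 10 at the dispersion of the real data, the test of that tumour against the other 3 recovered 8% of genes changed 4-fold and 64.3% of genes changed 16-fold, over 12839 genes, and called 0.01% of unchanged genes. With a dispersion of 0.05, it recovered 90% and 100% over 13022 genes. The dispersion of the real data used here was estimated over all 4 tumours as 1 group, so it counts the differences of tumour 10 as noise. The real test set that tumour apart and had a common dispersion of 0.191. The simulated recovery is therefore not that of the real test. The list scores were run on genes simulated as independent, with the real means and SDs of log2 CPM. There, random lists without a shift were called apart in 2 of 400 pairs of list and tumour, and a list shifted by 2 log2 units lay at percentile 100. That rate does not cover lists of co-regulated genes.

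The alternatives were DESeq2 1.42.0 and limma-voom (limma 3.58.1) as tests, DESeq2 size factors or total counts as scaling, each tumour's test adjusted alone, minimum means of 0.5 or 5 CPM, filterByExpr or no filter, a prior count of 0.5, a Poisson model with 5% technical variation, the median over list members, 5 bins, CPM per kilobase, and leaving out each tumour in turn. Matching random lists also on transcript length, the sum over rows, the removal of duplicated counts and, for the adult hepatocyte list, the removal of genes shared with the pericentral list were added after the data were seen. Gene lists and figures were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.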

Results

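The series holds 4 poly-A RNA libraries from mouse tumours, all with the same genotype label, MYC;PMEPA1 overexpression, in C57BL/6 animals. The genes were delivered by hydrodynamic tail vein injection, a rapid high-volume injection that carries plasmid DNA mainly into hepatocytes. MYC is a transcription factor that drives growth and ribosome production, and PMEPA1 is a membrane protein induced by TGF-beta that restrains TGF-beta signalling. The tumours carry the replicate numbers 1, 5, 9 and 10. The labels also give 8 to 10 passages, a term of cell culture, although the source is a tumour, and they do not say whether the tumours came from separate animals. All 4 libraries form 1 group with no control group, so no comparison between conditions was possible. The spread between tumours was the measurement, and it may include technical differences. Gene totals were 51939619, 41547970, 48931408 and 41948850 counts for tumours 1, 5, 9 and 10. At these depths, scaled by TMM, 3 counts correspond to 0.0524, 0.07, 0.0558 and 0.0892 counts per 1000000 (CPM). Such floors cover counting error only.

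The mouse genes of the delivered pair were expressed at low levels. Myc (NM_001177352, GRCm38 chromosome 15, 61985391 to 61990374, plus strand) had 4.86, 6.84, 8.58 and 7.40 CPM in tumours 1, 5, 9 and 10, a mean of 6.92 ± 1.56 CPM (SD, n = 4). These values rested on 278, 293, 461 and 249 counts. Pmepa1 (NM_022995, chromosome 2, 173224458 to 173276533, minus strand) varied more, with 2.43, 7.28, 4.19 and 0.922 CPM, a mean of 3.71 ± 2.73 CPM (SD, n = 4). Its counts were 139, 312, 225 and 31. Among expressed genes of the same tumour, Myc lay at percentile 24.2 ± 3.1 and Pmepa1 at percentile 14.7 ± 8.7 (SD, n = 4). By CPM per kilobase of transcript, they lay at percentiles 26.0 ± 3.8 and 9.8 ± 6.4 (SD, n = 4). Without a control group these levels say nothing about overexpression. The labels do not give the species of the delivered sequences, and reads from a human sequence may be counted only partly on a mouse gene. The Myc level also depends on the counting: the mean log2 CPM was 2.77 for its most abundant transcript row and 4.21 for the sum over its 4 rows.

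The most abundant transcripts came from fetal growth genes, from secreted liver proteins and from the translation machinery. H19, an imprinted non-coding RNA of fetal tissue (NR_001592, chromosome 7, 142575529 to 142578143, minus strand), was the highest of all genes, at 28150 ± 6985 CPM (SD, n = 4). Its imprinted neighbour Igf2, a fetal growth factor, had 5772 ± 2798 CPM. Albumin (Alb) had 7062 ± 4251 CPM, Apoe 5488 ± 3612, transferrin (Trf) 4835 ± 573 and Apoa1 3486 ± 1596. The elongation factors Eef1a1 and Eef2 had 9663 ± 2626 and 4059 ± 949 CPM, and the chaperone Hsp90ab1 had 3669 ± 309 (SD, n = 4 each). Rn45s, the ribosomal RNA precursor, had 11030 ± 2864 CPM, from 8662 in tumour 1 to 15120 in tumour 9. The libraries were selected for poly-A, so its level cannot be read as its expression. The 10 most abundant genes of each library took 7.41, 7.85, 8.84 and 9.84% of the gene counts.

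The tumours differed from each other far beyond counting error. Of 13129 expressed genes, 12952 (98.7%) varied more than a Poisson model allows at an adjusted p of 0.05, and 12359 did so when 5% of technical variation was added to the model. The median SD of log2 CPM was 0.45, and 2181 genes (16.6%) had an SD of at least 1. Tumours 1 and 5 were the most alike, with a Pearson correlation across genes of 0.955. Tumour 9 correlated with them at 0.891 and 0.888, and tumour 10 with tumours 1, 5 and 9 at 0.847, 0.844 and 0.832. These are correlations across genes, which are not independent replicates. No single gene passed the edgeR quasi-likelihood test of 1 tumour against the other 3, adjusted over all genes and the 4 tumours together: the counts were 0 for each tumour. At an unadjusted p of 0.05, the same test gave 94, 121, 743 and 2904 genes for tumours 1, 5, 9 and 10. Adjusted for each tumour alone, it gave 230 genes for tumour 10 and 0 for the others. The DESeq2 Wald test gave 29, 47, 331 and 1371 genes, and limma-voom gave 0 for each. Without tumour 9, tumour 10 had 411 genes, and without tumour 10, tumour 9 had 28. Each test treats the lone tumour as varying like the other 3, and it describes that tumour's library.

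Gene groups separated the tumours. The 25 gene lists with enough expressed members were scored in each tumour by the mean deviation of their members from the 4-tumour mean, against random lists matched on expression. Of 100 pairs of list and tumour, 45 lay among the lowest or the highest 0.5% of the random lists and are called apart, 22 above and 23 below, where 1 is expected if genes were independent. Genes of a list are co-regulated, so the percentiles describe these libraries and are not p-values. The 4 deviations of a list sum to 0, so a high tumour pushes the others down. Leaving out tumour 9 lowered the number of pairs apart to 26 of 75. Deviations also followed transcript length across genes, with Spearman's rho of 0.23, 0.14, 0.06 and -0.27 in tumours 1, 5, 9 and 10. With random lists matched on length too, 40 of the 45 pairs stayed apart; hepatocyte identity in tumours 1 and 9, proliferation in tumour 5 and MHC class II in tumours 5 and 9 did not.

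**Figure D1:**
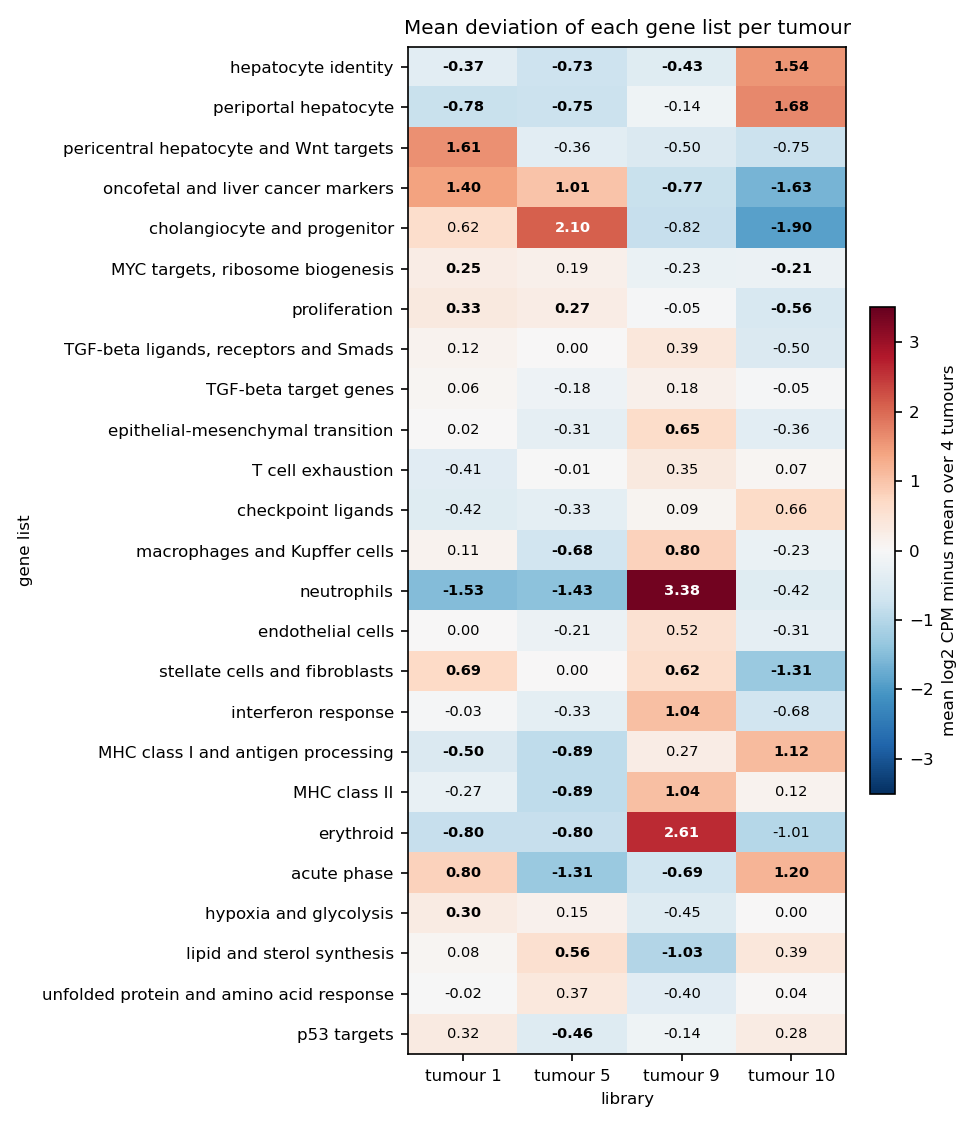
Mean deviation, in log2 CPM, of the expressed members of 25 gene lists (rows) in each of the 4 tumours (columns) from the mean over the tumours, with bold type for deviations among the lowest or the highest 0.5% of 10000 matched random lists. The neutrophil list in tumour 9 (3.38) is the highest value and the cholangiocyte and progenitor list in tumour 10 (-1.90) the lowest.

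Hepatocyte genes were highest in tumour 10. The hepatocyte identity list lay 1.54 log2 units above the 4-tumour mean there, at percentile 100, and 15 of its 18 genes were highest in that tumour. Its deviations were -0.37, -0.73 and -0.43 in tumours 1, 5 and 9, each apart on the low side. Alb had 13400 CPM in tumour 10 against 4732, 4520 and 5594 in tumours 1, 5 and 9. Tdo2, which starts tryptophan breakdown in hepatocytes, spanned the widest range of the list, with 1594 CPM in tumour 10 against 29.0, 2.22 and 2.77. Trf and Apoa1 did not follow: Trf was lowest in tumour 10, at 4112 CPM, and Apoa1 was highest in tumour 9, at 5779 CPM. All 12 periportal genes, those of the hepatocytes nearest the portal vein, were highest in tumour 10, with a list deviation of 1.68. The urea cycle genes Ass1 and Arg1 had 6825 and 2284 CPM there, against at most 1415 and 429 elsewhere. Pck1, the entry enzyme of gluconeogenesis, had 223 CPM in tumour 10 and 4.97 in tumour 5. Adjusted over the list alone, 11 of the 18 hepatocyte identity genes and 8 of the 12 periportal genes passed the edgeR test for tumour 10, and 0 passed over all genes. Ass1 shares its reads with the predicted gene Gm5424, so its count is uncertain. Without tumour 10, the hepatocyte identity list was no longer apart in tumours 1 and 9, where it lay at 0.15 and 0.08; with all tumours kept, the tumour 1 value was inside the limits with 5 bins (percentile 0.58) and the tumour 9 value with the median of members (-0.17).

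Fetal liver and liver cancer genes split the tumours into higher and lower ones, but not together. The oncofetal list of 12 expressed genes lay above the mean in tumours 1 (1.40) and 5 (1.01) and below it in tumours 9 (-0.77) and 10 (-1.63). Afp, the fetal counterpart of albumin (NM_007423, chromosome 5, 90490737 to 90508907, plus strand), had 1922, 3763 and 4974 CPM in tumours 1, 5 and 9 and 119.6 CPM in tumour 10. H19 and Igf2 went the other way, with 38040 and 9667 CPM in tumour 10, the highest of the 4. Lin28b, an RNA-binding protein of fetal cells, had 34.7, 14.8 and 11.3 CPM in tumours 1, 5 and 10. It had no count in tumour 9, which allows at most 0.0558 CPM. Named after their values were seen, Gpc3 had 82.8, 73.4, 5.53 and 0.535 CPM, Dlk1 825, 1310, 149 and 2.41, and Peg3 124, 60.8, 9.85 and 0.743 in tumours 1, 5, 9 and 10, while Igf2bp1 had 7.30 CPM in tumour 1 and at most 0.168 elsewhere. Adjusted over the list alone, 8 of the 12 genes passed the edgeR test for tumour 10, and 0 over all genes. The low value in tumour 9 was no longer apart without tumour 1 (-0.38), without tumour 5 (-0.44) or with the median of members (-0.33).

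Bile duct and progenitor genes were highest in tumour 5. The cholangiocyte and progenitor list of 8 expressed genes lay at 2.10 in tumour 5, where 5 of the 8 were highest, and at -1.90 in tumour 10. Prom1, a progenitor surface protein, had 40.0 CPM in tumour 5 and 0.595 in tumour 10. Krt19, a bile duct keratin, had 11.5 CPM in tumour 5 and 0.0297, or less than 3 counts, in tumour 10. Spp1 did not follow this order and was highest in tumour 1, at 33.5 CPM. The low value in tumour 10 was no longer apart without tumour 5 (-1.18).

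Genes of pericentral hepatocytes, the cells nearest the central vein that depend on Wnt signals, were highest in tumour 1. This list lay at 1.61 there, with 8 of 11 expressed genes highest in tumour 1, and was apart in no other tumour. Some markers of normal adult liver cells were also high in tumour 1. A list of 21 genes abundant in adult hepatocytes, added after the values of many of them were seen, lay at 1.27 in tumour 1 and 1.08 in tumour 10, both at percentile 100, with 9 and 11 of its genes highest in these tumours. Its members Mug1, Cyp2c29, Cyp2c50, Cyp1a2, Akr1c6, Gulo and Ces3a were highest in tumour 1 and had been seen before the list was written. The score in tumour 1 is therefore no independent check. The list lay at -0.78 in tumour 5 and -1.57 in tumour 9, both at percentile 0. It shares 2 genes with the pericentral list and lay at 1.11 in tumour 1 without them. Mug1 had 98.7 CPM in tumour 1 against at most 10.5 elsewhere, and Cyp2c29 18.7 against at most 1.59. The resident Kupffer cell markers Clec4f, Marco and Timd4 had 20.7, 8.67 and 1.80 CPM there, against at most 2.99, 2.68 and 0.420 elsewhere. The sinusoidal endothelial markers Clec4g and Oit3 had 2.25 and 4.39 CPM against at most 0.350 and 1.47, and the stellate cell marker Lrat 3.25 against at most 1.21. Of these markers, all but Clec4f were chosen after their values were seen. The whole macrophage and Kupffer cell list lay at 0.11 in tumour 1, at percentile 73.83, with 12 of 16 genes below the 4-tumour mean, and the endothelial list at 0.00, at percentile 42.11, with 10 of 14 below, while the stellate cell and fibroblast list was apart (0.69, and 0.26 and inside the limits without tumour 10). Glul, glutamine synthetase, had 291 CPM in tumour 1 and 161, 247 and 104 in tumours 5, 9 and 10. Slc1a2, a glutamate transporter, had 11.1 CPM in tumour 1 and at most 0.8003 elsewhere. Cyp2e1 was as high in tumour 10 (203 CPM) as in tumour 1 (205 CPM), and Cyp27a1 was highest in tumour 10, at 234 CPM. Adjusted over the list alone, 2 pericentral genes passed the edgeR test for tumour 1 and 2 for tumour 10, and 0 over all genes; at an unadjusted p of 0.05, 2 and 4 did so. Without tumour 9, the adult hepatocyte list lay at 0.77 in tumour 1, still at percentile 100, and at 0.53 in tumour 10, no longer apart; in tumour 10 it lay at 1.75 without tumour 1 and at 2.13 with the median of members.

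**Figure D2:**
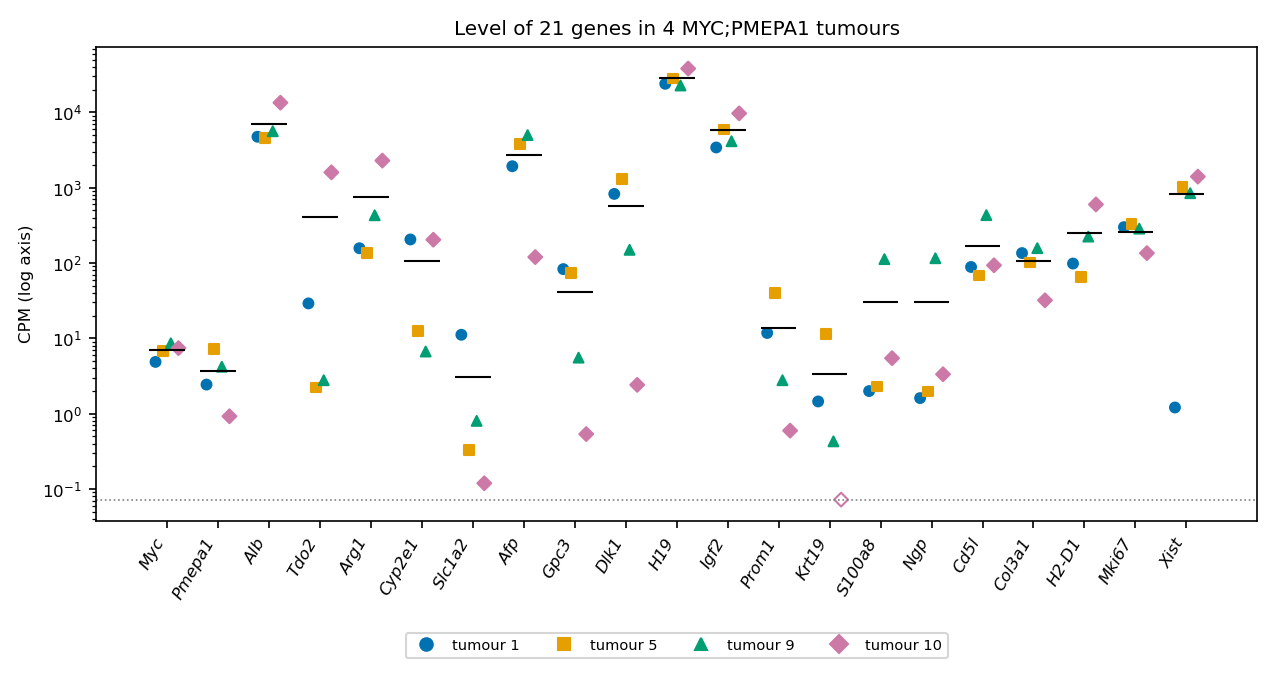
Level of 21 genes (horizontal axis) in CPM on a log axis, with 1 symbol per tumour and a black line at the mean of the 4 tumours. Open symbols at the dotted line (0.0722 CPM) stand for less than 3 counts. Afp, Gpc3 and Dlk1 lie lowest in tumour 10 while H19 and Igf2 lie highest there, and Xist lies at 1.21 CPM in tumour 1 against 843 CPM or more in the others.

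Neutrophil and red cell genes were high in tumour 9. All 12 expressed neutrophil genes were highest there, with a list deviation of 3.38, and all 12 passed the edgeR test for tumour 9 when adjusted over the list alone, against 0 over all genes. The calcium-binding proteins S100a8 and S100a9 had 112 and 140 CPM in tumour 9 against at most 5.44 and 6.78 elsewhere, and the granule protein Ngp had 115 against at most 3.33. Cxcr2, Retnlg, Mmp8, Camp, Il1r2 and Padi4 passed the filter of 1 CPM only through tumour 9, which favours a high score there. S100a8, S100a9, Ngp, Csf3r, Ltf and Mpo had a mean above 1 CPM over the other tumours too. The erythroid list lay at 2.61 in tumour 9, with all 10 genes highest and 9 passing over the list alone. Hbb-bs, a beta globin, had 366 CPM against at most 82.0, and Kel 13.1 against at most 3.27. Hba-a1 and Hba-a2 both had 257 CPM because they share their reads. The neutrophil list lay at -1.53 and -1.43 in tumours 1 and 5 and the erythroid list at -0.80 in each, all apart. Without tumour 9, the neutrophil list lay at -0.38 and -0.10 in tumours 1 and 5, and the erythroid list at 0.13 and 0.10, none of them apart. With duplicated counts removed, the erythroid value of tumour 5 was inside the limits (percentile 0.58).

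Macrophage and interferon genes were also high in tumour 9. The macrophage and Kupffer cell list lay at 0.80 in tumour 9, where 10 of 16 genes were highest, and at -0.68 in tumour 5. Cd5l had 431 CPM in tumour 9 against at most 93.0 elsewhere, and the complement genes C1qb and C1qc had 140 and 143. Clec4f, which marks resident Kupffer cells, went the other way, with 20.7 CPM in tumour 1 and 0.745 in tumour 9. The low macrophage value of tumour 5 was no longer apart without tumour 9 (-0.41). The interferon list lay at 1.04 in tumour 9, with 13 of 17 genes highest there, and Ifit3 had 9.87 CPM against at most 2.57 elsewhere. Bst2 and Usp18 were highest in tumour 10, at 241 and 79.98 CPM, and Cxcl10 was lowest there, at 12.5 CPM. MHC class II genes lay at 1.04 in tumour 9 and -0.89 in tumour 5, and Cd74 had 35.9 and 9.92 CPM in these tumours, H2-Ab1 17.9 and 4.18, H2-Eb1 16.7 and 3.76, and H2-Aa 16.7 and 3.43. The class II value of tumour 9 was at percentile 99.58 and fell inside the limits under 6 of the alternatives. That of tumour 5 did so without tumour 9 (-0.54), with length matching (percentile 1.04) and with the sum over rows (percentile 0.59).

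MHC class I genes, which present peptides to cytotoxic T cells, departed from the interferon list in tumour 10. They were highest in tumour 10, at 1.12, where the interferon list lay at -0.68, inside the limits. In tumour 9 they lay at 0.27, also inside the limits, and they lay at -0.89 in tumour 5 and -0.50 in tumour 1. H2-D1 had 598 CPM in tumour 10 and 65.3 in tumour 5, H2-K1 423 and 82.1, and B2m 469 and 137. Nlrc5, the activator of class I genes, had 15.1 CPM in tumour 10 and 0.934 in tumour 5. Class I genes are a family of near-identical sequences, so reads may be shared among them. The tumour 1 value ended inside the limits under 5 of the alternatives, and lay at -0.12 without tumour 10.

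T cell genes were near the detection floor in all 4 tumours. Of 16 measured T cell genes, 2 had a mean of at least 1 CPM, Cd247 and Cd4, and the list medians were 0.140, 0.117, 0.363 and 0.178 CPM in tumours 1, 5, 9 and 10. None of 15 cytotoxic and NK cell genes reached a mean of 1 CPM, with medians of 0.157, 0.0934, 0.261 and 0.149 CPM. B and plasma cell genes had medians of at most 0.140 CPM, with 2 of 13 expressed, Cd22 and Mzb1. Dendritic cell genes had medians of at most 1.15 CPM, with 4 of 12 expressed, led by Fscn1 (7.27 ± 1.27 CPM), Itgax (4.22 ± 2.12) and Cd83 (3.72 ± 2.40, SD, n = 4 each). Regulatory T cell genes had medians of at most 0.372 CPM. Foxp3, their defining factor, stood at 13.1 ± 1.70 CPM, while Tnfrsf18 and Tnfrsf4 had 1.71 ± 0.601 and 1.49 ± 0.294 CPM (SD, n = 4 each). Only these 3 of the 10 regulatory T cell genes were expressed, and Il2ra and Ikzf2 had at most 0.279 and 0.465 CPM. The Foxp3 level therefore does not show that regulatory T cells were present. These 5 lists had too few expressed genes to be scored.

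The T cell exhaustion list was apart in no tumour, with deviations of -0.41, -0.01, 0.35 and 0.07. Only 6 of its 16 genes were expressed: Entpd1, Nr4a1, Nr4a2, Cd200, Havcr2 and Tox. Entpd1, an enzyme that breaks down extracellular ATP, had 18.9 ± 11.7 CPM, Nr4a1 11.4 ± 6.11 and Nr4a2 7.07 ± 3.93 (SD, n = 4 each), and these genes are also expressed outside T cells. Tox had 1.10, 2.498, 0.391 and 0.119 CPM. The checkpoint receptor genes Pdcd1 and Ctla4 had at most 0.208 and 0.558 CPM in any tumour. Checkpoint ligand genes were apart in no tumour, with deviations of -0.42, -0.33, 0.09 and 0.66; the value in tumour 1 fell outside the limits when the median replaced the mean (-0.56). Lgals9, coding for galectin-9, had 313 ± 77.2 CPM, Fgl1 40.2 ± 28.7 and Pvr 32.0 ± 6.92 (SD, n = 4 each). Cd276 had 23.8 and 32.3 CPM in tumours 5 and 10 against 2.94 and 1.97 in tumours 1 and 9.

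TGF-beta genes did not separate the tumours as a group. The 22 TGF-beta target genes had deviations of 0.06, -0.18, 0.18 and -0.05 in tumours 1, 5, 9 and 10, all inside the limits, and 6, 3, 7 and 6 of them were highest in these tumours. The highest were Tgm2 (260 ± 92.8 CPM), Cdkn1c (129 ± 78.1) and Bhlhe40 (106 ± 69.9, SD, n = 4 each). Single targets went opposite ways: in tumour 9, Ctgf, Cyr61 and Tgfbi were highest of the 4 tumours, at 44.9, 26.3 and 25.3 CPM, while Bhlhe40, at 42.9 CPM, was lowest. Sphk1 varied most, with 4.78 CPM in tumour 9 and at most 0.677 elsewhere. Ligands, receptors and Smads had deviations of 0.12, 0.00, 0.39 and -0.50, also inside the limits. Smad4 had 80.03 ± 7.87 CPM, Smad2 35.9 ± 5.18 and the receptor Tgfbr1 42.0 ± 14.5 (SD, n = 4 each). Tgfb1, Tgfbr2 and Ltbp1 were highest in tumour 9, at 27.6, 42.2 and 2.40 CPM. No gene of either list passed the edgeR test in any tumour, over the list alone or over all genes; at an unadjusted p of 0.05, 0, 1, 5 and 5 of the targets and 0, 0, 1 and 4 of the 15 expressed ligands, receptors and Smads did so in tumours 1, 5, 9 and 10.

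**Figure D3:**
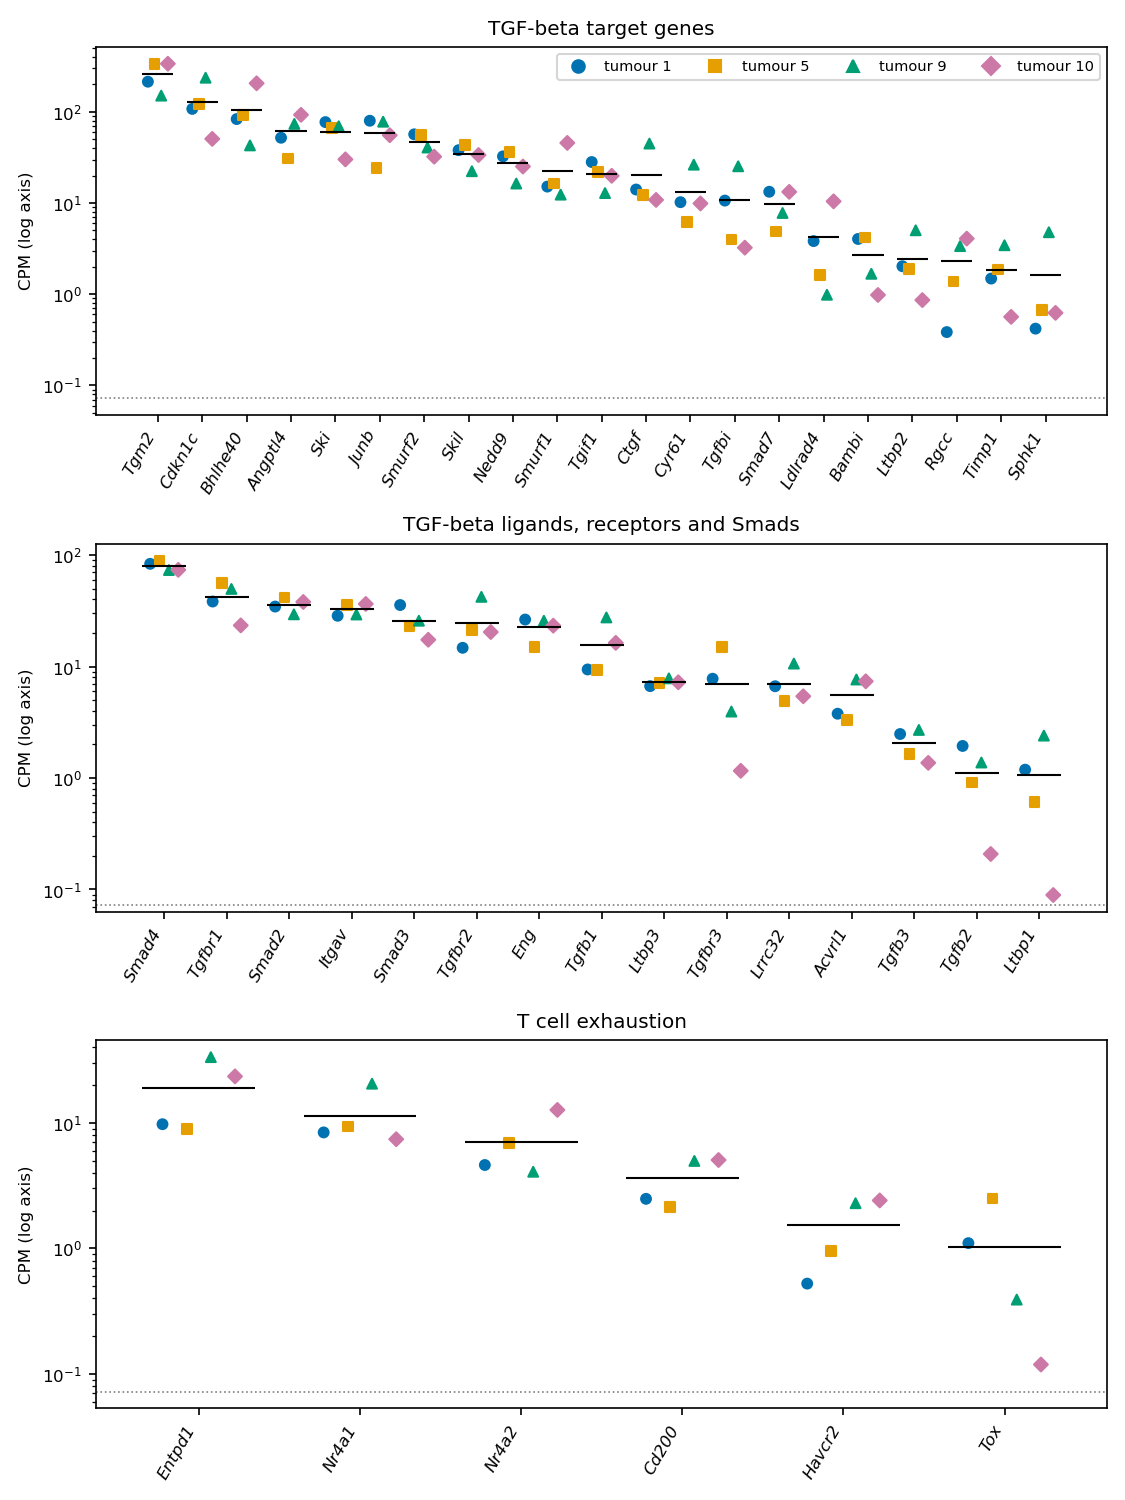
Levels of expressed members of 3 gene lists (TGF-beta targets, TGF-beta ligands, receptors and Smads, and T cell exhaustion genes) in CPM on a log axis, with 1 symbol per tumour and a black line at the mean of the 4 tumours. The dotted line, at 0.0722 CPM, is 3 counts over the unscaled gene total of tumour 5. Tumour 9 is the highest for Ctgf, Cyr61 and Tgfbi (44.9, 26.3 and 25.3 CPM) and the lowest for Bhlhe40 (42.9 CPM).

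Stromal collagen genes were low in tumour 10. The stellate cell and fibroblast list lay at -1.31 there, with 15 of 17 genes lowest, and at 0.69 and 0.62 in tumours 1 and 9. Col3a1 had 31.9 CPM in tumour 10 against 135, 101 and 157 in tumours 1, 5 and 9, Col1a1 26.9 against 101, 62.8 and 115, and Col1a2 29.7 against at least 76.5. Reln had 9.16 CPM in tumour 1 and 0.0892 in tumour 10. Adjusted over the list alone, 6 of the 17 passed the edgeR test for tumour 10, and 0 over all genes. Without tumour 10, the list lay at 0.26 and 0.18 in tumours 1 and 9 and was not apart; with 5 bins, the tumour 9 value was also inside the limits (percentile 99.24). Epithelial-mesenchymal transition genes lay at 0.65 in tumour 9, the tumour with high neutrophil genes, and the widest ranging member, Mmp9 (13.1 CPM there, at most 0.714 elsewhere), is also a neutrophil product. The value was inside the limits with the median of members (0.25) and with the sum over rows (percentile 99.32). Fn1 had 353 ± 118 CPM, Sparc 144 ± 30.8 and Cdh2 127 ± 28.4 (SD, n = 4 each). Endothelial genes were apart in no tumour, with Cdh5 at 25.6 ± 5.06, Pecam1 at 23.3 ± 7.79 and Plvap at 23.4 ± 6.70 CPM. Lyve1 was lowest in tumour 10, at 0.238 CPM.

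Cell cycle genes were lower in tumour 10. The proliferation list lay at -0.56 there, with 14 of 18 genes lowest, and at 0.33 and 0.27 in tumours 1 and 5. Mki67 had 135 CPM in tumour 10 against 299, 326 and 285 in tumours 1, 5 and 9, and Top2a 92.7 against 328, 285 and 209. Ccna2 had 194 ± 33.3 CPM (SD, n = 4). Adjusted over the list alone, 4 of the 18 passed the edgeR test for tumour 10. Without tumour 10, the list lay at 0.15 and 0.08 in tumours 1 and 5, inside the limits. MYC target genes of ribosome biogenesis differed little: the list lay at 0.25 in tumour 1 and -0.21 in tumour 10, both apart, and at 0.19 and -0.23 in tumours 5 and 9. The tumour 10 value was at the limit, at percentile 0.5, with the sum over rows and no longer counted as apart. Npm1 had 1878 ± 138 CPM, Ncl 1873 ± 406 and Hspd1 1657 ± 252 (SD, n = 4 each), and Bop1 varied most, from 81.1 CPM in tumour 9 to 301 in tumour 10.

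Acute phase genes, which the liver raises in inflammation, were high in tumours 1 (0.80) and 10 (1.20) and low in tumours 5 (-1.31) and 9 (-0.69). Haptoglobin (Hp) had 685, 71.5, 124 and 5815 CPM in tumours 1, 5, 9 and 10, and Saa2 10.96, 0.257, 0.149 and 17.5. Itih3 was highest in tumour 9, at 1259 CPM, and Hpx had 958 ± 328 CPM (SD, n = 4). The value of tumour 9 was no longer apart without tumour 1 (-0.42) or tumour 10 (-0.29), nor with the median of members (-0.12). Lipid and sterol synthesis genes lay at 0.56 in tumour 5 and -1.03 in tumour 9, where 12 of 16 genes were lowest. Fasn, fatty acid synthase, had 995, 865, 264 and 714 CPM, and Acly 346, 415, 163 and 328. Scd1 and Me1 were highest in tumour 10, at 778 and 139 CPM.

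Glycolysis genes lay slightly high in tumour 1 (0.30), and this list was apart in no other tumour. The value was inside the limits without tumour 9 (0.17), with a minimum mean of 0.5 CPM (0.25) and with 5 bins (percentile 99.29). Pkm had 2092 and 1710 CPM in tumours 1 and 5 against 490.3 and 613 in tumours 9 and 10, and Ldha was lowest in tumour 10, at 1055 CPM against at least 2794. Eno1 had 2571 ± 634 CPM (SD, n = 4) and shares reads with Eno1b. The unfolded protein and amino acid response list was apart in no tumour, with Hsp90b1 at 1104 ± 51.3 and Hspa5 at 976 ± 106 CPM (SD, n = 4 each). Psat1, an enzyme of serine synthesis, had 1324, 1711, 784 and 177 CPM. The p53 target list lay at -0.46 in tumour 5; Cdkn1a had 143 ± 48.9, Btg2 119 ± 77.2 and Bax 102 ± 7.07 CPM (SD, n = 4 each), and Eda2r 0.210 CPM in tumour 5 and 6.69 in tumour 10. The p53 value was inside the limits with the median of members (-0.20) and without tumour 1 (-0.35).

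Other tissues left few transcripts. Of 11 pancreatic acinar genes, 2 were expressed, Cela1 (11.9 ± 6.65 CPM) and Cela2a (1.66 ± 0.156), and of 7 measured mesothelial genes also 2, Upk3b (3.31 ± 3.69) and Msln (1.05 ± 0.774, SD, n = 4 each). Xist, the RNA that silences 1 X chromosome in female cells (NR_001463, chromosome X, 103460366 to 103483254, minus strand), had 1022, 843 and 1399 CPM in tumours 5, 9 and 10 and 1.21 CPM, from 69 counts, in tumour 1. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in all 4 tumours.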

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

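The tests on dilution, adult hepatocytes, blood cells, spleen or marrow, the Y chromosome and the loss of an X were chosen only after the pattern they address was seen; those on transcript length and on X reactivation were written down before their result was seen. The measure used here asks whether 1 tumour lies far from the other 3, with a gap to its neighbour, as a share of the whole range, above Dixon's 95% critical value for 4 samples. Chance gives such a gap in about 1 in 20 groups of 4. It appeared for 10 of 116 genes taken for a high mean or the largest SD, for 8 of 45 other named genes, for 3 of 25 gene lists and for none of 4 library measures. The gene counts cannot be set against that chance rate, because the first set includes genes taken for their spread and many of the others were chosen after their values were seen. Genes of a list move together, so these are fewer independent events than they seem.

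Tumour 10 lay far from the others for the hepatocyte identity list (1.54 log2 units above the mean), Ass1 (6825 CPM), Eef1a1 (13584 CPM), Bhmt (2798 CPM), Slco1b2 (425 CPM) and Ces2g (250.0 CPM) on the high side. On the low side it did so for Mki67 (135 CPM), Ldha (1055 CPM) and Rtl1 (0.0595 CPM). Dilution of the tumour by non-tumour adult liver would lower the oncofetal and the cell cycle genes by about the same factor. Afp differed by -4.79 log2 units from the mean of the other tumours, but the proliferation genes had a median difference of -0.76 (quartiles -1.15 and -0.38). Of the 12 expressed oncofetal genes, 8 were below the mean of the others. The other 4 were above it: H19, Igf2 and Igf2bp3, by 0.62, 1.15 and 0.39, and Lin28b, by 2.02. Lin28b was above the log2 mean only because tumour 9 had no count. Its 11.3 CPM in tumour 10 lay below the 34.7 and 14.8 CPM of tumours 1 and 5. The values of the proliferation genes, H19, Igf2 and Igf2bp3 argue against dilution as the whole cause. The test was chosen after the pattern was seen and is no independent check. Adult hepatocytes in the sample would bring all their abundant transcripts. Of 21 genes abundant in adult hepatocytes, 8 were not above the median of the other tumours, among them Mug1 at 1.46 CPM and Cyp2c29 at 0.416 CPM. These 8 had been seen before the list was written, and the other 13 were above that median. The list therefore cannot decide on adult hepatocytes as the whole cause, and this stays open. That list as a whole lay at 1.08 in tumour 10, at 2.13 with the median of members, at 1.75 without tumour 1 and, no longer apart, at 0.53 without tumour 9. Deviations in tumour 10 fell with transcript length across genes (Spearman's rho -0.27), but the hepatocyte list stayed at percentile 100 among lists matched on length too, where the highest random list reached 0.98. A less fetal, more mature hepatocyte state in tumour 10 remains a hypothesis, and the higher H19, Igf2 and Igf2bp3 go against its less fetal part. No biological explanation was tested because the labels give no difference between the tumours.

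Tumour 9 lay far from the others for the erythroid list (2.61), Hba-a1 and Hba-a2 (257 CPM each), the neutrophil granule genes Ngp (115 CPM) and Mpo (64.8 CPM), the macrophage gene Cd5l (431 CPM), the blood precursor genes Gfi1 (2.36 CPM) and Myb (3.54 CPM), the interferon-induced Rsad2 (26.9 CPM) and, at 0 counts, Lin28b (0 CPM). Circulating mature blood cells lack the transcripts of their precursors, but 6 precursor genes whose values had not been seen (Ms4a3, Gfi1, Gfi1b, Rhag, Ermap and Myb) had a median difference of 5.46 log2 units and were all highest in tumour 9, which argues against mature blood as the whole cause. Spleen or bone marrow tissue would bring B cells, but 8 B lineage genes had a median difference of 0.23 and reached at most 2.33 CPM, while the neutrophil genes had a median difference of 4.86. Blood formation within this tumour may account for the pattern; it was not tested further, and no biological difference between the tumours is given.

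Tumour 1 lay far from the others for Xist, at 1.21 CPM, and for the pericentral hepatocyte and Wnt target list (1.61). The adult hepatocyte list was also high there (1.27, percentile 100, with 9 of 21 genes highest). Its members Mug1, Cyp2c29, Cyp2c50, Cyp1a2, Akr1c6, Gulo and Ces3a were highest in tumour 1 and had been seen before the list was written. The list is therefore no independent check for this tumour. Some markers of resident Kupffer, sinusoidal and stellate cells were high there too: Clec4f (20.7 CPM), Marco (8.67), Timd4 (1.80), Clec4g (2.25), Oit3 (4.39), Lrat (3.25) and Reln (9.16). All of these markers but Clec4f and Reln were chosen after their values were seen. The fixed macrophage and Kupffer cell list (0.11, percentile 73.83) and the endothelial list (0.00, percentile 42.11) were not apart in tumour 1, and Cd5l was highest in tumour 9. The fixed stellate cell and fibroblast list was apart in tumour 1 (0.69, percentile 99.97), but not without tumour 10 (0.26). A male animal would explain the missing Xist; the 4 Y-linked genes had 0 counts in tumour 1, but so did all 44 measured genes on chromosome Y in every library, so it is not shown that reads from the Y chromosome were counted at all, and this stays open. Reactivation of the silent X would raise X-linked genes, but their median excess over autosomal genes in tumour 1 was 0.10 (bootstrap 95% interval 0.04 to 0.17), below the bound of 0.2 set beforehand. That bound took no account of the spread between tumours: tumours 5, 9 and 10, with Xist, had 0.16, 0.09 and -0.31, an SD of 0.25 (n = 3), so the test does not decide and reactivation stays open. Loss of 1 X copy would lower genes that escape silencing; 7 such genes lay at percentile 4.91 among random X-linked lists, with a mean difference of -0.27, which does not pass the bound set for either outcome, and some of their values had been seen. A male animal, the loss of 1 X in a female and reactivation therefore cannot be told apart here.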

How the results depend on the processing

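Matching on transcript length, the sum over transcript rows, the removal of duplicated counts and that of genes the adult hepatocyte list shares with the pericentral list were chosen after the data were seen; the other alternatives were fixed before. The numbers of expressed genes and of genes beyond counting noise stayed within 1.5 times the reported counts in every alternative run (10728 to 19162 and 12284 to 15790). The counts of genes in the tests of 1 tumour against the other 3 did not: reported as 0, they were 29, 47, 331 and 1371 with DESeq2's Wald test for tumours 1, 5, 9 and 10; 2, 0, 6 and 121 without a low-count filter; and 230 for tumour 10 adjusted alone. Leaving out another tumour gave 0 to 2 genes for tumour 1, 0 to 1 for tumour 5, 0 to 28 for tumour 9 and 0 to 411 for tumour 10. The cause was not tested. Of 45 list and tumour pairs apart, 23 stayed apart under every setting. The number apart ranged from 41 to 51 over the alternatives that keep all tumours and from 26 to 40 without 1 tumour, where fewer pairs are tested. With length matching, 40 of the 45 stayed apart. Leaving out a tumour also turned 4 called values, since it changes the mean they are measured from. Without replicate 10, hepatocyte identity in tumours 1 and 9 turned from -0.37 and -0.43 to 0.15 and 0.08. Without replicate 9, erythroid genes in tumours 1 and 5 turned from -0.80 in each to 0.13 and 0.10. With each other tumour left out in turn, these 4 values ranged from -0.62 to 0.15, -0.68 to 0.08, -1.13 to 0.13 and -1.14 to 0.10. The mean log2 CPM of Myc moved to 4.21 with the sum over rows, where reads on shared exons count more than once; Pmepa1 stayed within 1 SD. Of 1288 recomputed levels of 161 named genes, 41 moved by 1 SD or more, 36 of them under the sum over rows and 5 without replicate 10. No paired analysis was possible because there is only 1 group.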

Other observations

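The genes and lists here were chosen after the values of many of them were seen, and only the circadian list was scored. Meg3, Rian, Mirg and Rtl1, imprinted genes of the Dlk1-Dio3 region of chromosome 12, were lowest in tumour 10. Meg3 (NR_003633, 109541001 to 109571726, plus strand) had 246, 271, 119 and 2.35 CPM in tumours 1, 5, 9 and 10, and Rian had 300, 357, 108 and 1.10. Mirg and Rtl1 had 0.0595 CPM each in tumour 10, less than 3 counts, against at least 4.84 and 3.39 in the others. H19 and Igf2, the imprinted pair of chromosome 7, were highest in the same tumour. In tumour 10, Sult2a1 had 358 CPM against at most 7.89, Cyp2b10 80.5 against at most 0.747, Adh1 1716 against at most 572, and Slco1b2, which takes bile acids into hepatocytes, 425 against at most 36.1. In tumour 1, Cyp1a2 had 25.4 CPM against at most 2.38 elsewhere, Cyp2c29 18.7 against at most 1.59, Cyp2c50 18.3 against at most 1.68, Akr1c6 35.2 against at most 4.65 and Cyp2b9 4.21 against at most 0.186.

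Foxp3 (13.1 ± 1.70 CPM) and Cd247 (11.6 ± 3.54 CPM, SD, n = 4 each) stood far above the other T cell genes, with Cd3e at most 0.335 CPM in any tumour. Whether their reads came from T cells was not tested. Cd274, coding for the checkpoint ligand PD-L1, had 2.31, 1.68, 6.48 and 8.39 CPM in tumours 1, 5, 9 and 10. A list of 13 expressed circadian clock genes lay at 0.18 in tumour 1, at percentile 92.42, and was apart in no tumour.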
